A study of Danio rerio with 6 samples.

How the data were processed

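Gene expression was measured on zebrafish 3' expression arrays with 1 value per probe set and array. The 6 arrays were grouped by their titles and the series design into unirradiated collecting ducts, irradiated collecting ducts and whole kidney, with 2 arrays each. The irradiated group was recognised by a prefix in the sample titles together with the design text, which gives the dose of 25 Gy. Each array held RNA from a pool of 5 fish, described as independent. The labels give no time after irradiation, age, sex, hybridisation date or labelling batch.

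The values were log2 expression values that the authors made with RMA and the affy package, per the labels' processing notes, which state no versions. RMA corrects the background, normalises quantiles across arrays and summarises the probes of a probe set. The deposited values ran from 2.20 to 14.5 with nearly equal medians in the 6 arrays. No value was transformed further. Scanner files were not used here. The number of arrays limits the precision of every value.

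Of 15617 probe sets, 115 array controls were left out of the tests, and 15502 were tested. Gene symbols came from the platform's probe table and were brought up to date through a current zebrafish gene table, which was used for names alone. Of the tested probe sets, 10795 named 1 gene, 135 named several and 4572 named none. They covered 8793 genes, of which 634 had symbols that only number a clone or locus and were counted but not named. No genome sequence or coordinates were used.

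Groups were compared with limma (version 3.58.1) in R (version 4.3.3), with 1 mean per group, all 6 arrays in 1 fit and 3 residual degrees of freedom. The empirical Bayes prior had 2.83 degrees of freedom. P values were two-sided and adjusted by Benjamini-Hochberg over the tested probe sets of a comparison, and an adjusted p under 0.05 counted as past the threshold. SE is the moderated standard error of a log2 fold change. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so it was not used.

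Before the data were examined, 25 gene lists of cell types and pathways, the rule for named genes, the tests of probe sets and lists, and the alternatives were fixed. Some tests of explanations were chosen later, as said where they appear. A gene was represented by its probe set with the highest mean over all arrays. The rule took the promoter gene f11r.1, then, per comparison, up to 12 genes with the largest and 12 with the lowest log2 fold change among those past the threshold with a change of at least 1 on the log2 scale and no overlap between the groups. A direction with fewer than 6 was filled to 6 by the smallest p. Up to 4 members of each list followed, those past the threshold first. Genes named outside this rule are said to be so where they appear.

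The lists had 1236 entries, of which 27 were matched by a synonym and 387 were not on the array. A synonym pointing to an unrelated gene was dropped in 3 cases, chosen after the matches and their values had been looked at. Lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. A second camera run estimated the correlation from the residuals, and fry was run as well. That camera run also takes its p from the 3 residual degrees of freedom, so a higher p need not come from correlation. Lymphoid genes in irradiated against unirradiated ducts had an estimated correlation of -0.0819, under the preset. Their camera adjusted p still went from 0.00176 to 0.465. Niche (-0.018) and proton pump genes (-0.0372) in ducts against kidney also lost their calls. Each list's counts are given over all probe sets and adjusted over the list alone. All 25 lists are covered in both main comparisons.

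The fit was tested on simulated data with known changes, 5 times per comparison. A log2 change of 2 was found in 68.0%, 62.8% and 69.6% of cases for unirradiated ducts against kidney, irradiated against unirradiated ducts, and irradiated ducts against kidney. A change of 1 was found in 11.2%, 0.8% and 5.2%. False calls made up 8.76%, 1.04% and 11.4% of calls. For lists shifted by 0.5, camera with the preset correlation called 98% and, where genes were simulated with a correlation of 0.2, also 46 of 200 lists that had not been shifted. With an estimated correlation it called 62% of shifted lists without simulated correlation, 8% with it, and 0 of the lists that had not been shifted. Each probe set simulation changed only 200 of 15502 probe sets, so its rates need not hold where many change. The list simulation gave all groups the same spread. Some real lists had a higher estimated correlation, as proliferation (0.572), skeletal muscle (0.53) and erythroid genes (0.444). False calls may be more frequent for those than simulated.

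The alternatives were the replicate number as a block, a fit on the compared groups alone, eBayes with trend and robust, array weights, a filter at a mean log2 of 5, centring on 9 hybridisation control probe sets, an adjusted p under 0.1, a test against a fold of 1.5, gene-level medians, and leaving out each array in turn. A group left with 1 array was assumed to vary like the others. Irradiated ducts against whole kidney are given as counts with genes already named.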

Results

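Gene expression was profiled on 6 zebrafish 3' expression arrays, each hybridised with RNA pooled from 5 adult fish that carry EGFP under the promoter of jam1a, a tight junction gene now named f11r.1. Collecting ducts, the last segment of the renal tubule, were dissected by their fluorescence from unirradiated fish and from fish given 25 Gy of X-rays. Whole kidney, which in fish is also the main site of adult blood formation, served as the tissue for comparison. Each of the 3 groups had 2 arrays, and this small number limits the precision of every value. Levels are log2 RMA values given as mean ± SD, and fold changes come from limma with Benjamini-Hochberg adjustment over 15502 probe sets. Levels under the array medians, 5.82 to 5.88, are not shown to be above background, so the size of any fold change against such a level is uncertain. The time between irradiation and dissection is not given in the sources used here.

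The gene behind the reporter was measured first. The f11r.1 probe set read 11.54 and 11.39 in the unirradiated ducts, 11.59 and 11.56 in the irradiated ducts, and 10.36 and 10.20 in whole kidney. It was 2.28-fold higher in unirradiated ducts than in whole kidney (log2 fold change 1.19 ± 0.16 SE, adjusted p = 0.0172). With each array centred on its hybridisation controls the sign turned (-0.36, adjusted p = 0.682). This centring lowers every log2 fold change of the comparison by 1.55, so any smaller rise turns by construction. The controls themselves averaged 8.48 and 10.24 in the 2 kidney arrays. The adjusted p was 0.114 and 0.1 without unirradiated duct replicates 1 and 2, and 0.0537 without either irradiated array. After irradiation f11r.1 differed by 0.11 ± 0.16 (adjusted p = 0.794), which is less than its standard error.

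The first comparison asked which transcripts set collecting ducts apart from whole kidney, a tissue that holds the ducts as well. Ducts held far more of several epithelial transcripts. The calcium-binding protein gene s100w was at 11.38 ± 0.23 (SD, n = 2) in ducts and 5.46 ± 0.83 in whole kidney, a log2 fold change of 5.92 ± 0.47 (adjusted p = 0.00591). The forkhead transcription factor foxa1 was 21.5-fold higher (log2 fold change 4.43 ± 0.25, adjusted p = 0.00374), and the genes for sciellin (scel) and envoplakin (evplb), proteins of stratified epithelial envelopes, were higher by 4.63 ± 0.31 and 4.17 ± 0.32 on the log2 scale. All 4 genes had group means under the array medians in whole kidney, so the sizes of these differences are uncertain. The alanine aminotransferase gene gpt was 8.31-fold lower (-3.05 ± 0.44, adjusted p = 0.02). In all, 662 probe sets were higher in ducts and 464 lower, of which 593 and 371 changed at least 2-fold.

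Other genes with the largest positive fold changes were rims2a, which encodes a protein of synaptic release sites (5.32 ± 0.37), the fucosyltransferase gene fut9b.4 (4.54 ± 0.25), the calpain protease gene capn9 (4.47 ± 0.44), cuzd1.1 (4.20 ± 0.53) and the annexin gene anxa1c (4.15 ± 0.57). Genes of muscle filaments stood among them, namely desmb, which encodes desmin (4.56 ± 0.38), and smtnb, the gene of smoothelin (4.16 ± 0.36). The immediate early transcription factor gene fosab was 26.1-fold higher (4.71 ± 0.40). Adjusted p of these 8 genes lay between 0.00374 and 0.019. At the other end, the parvalbumin gene pvalb6 had the lowest log2 fold change (-3.34 ± 0.63), followed by hgd, the homogentisate dioxygenase gene of tyrosine breakdown (-3.07 ± 0.49), gpt, the lipoxygenase gene alox5b.3 (-2.96 ± 0.44) and hoga1, an enzyme gene of hydroxyproline breakdown (-2.91 ± 0.46). The blood zinc finger gene drl (-2.88 ± 0.56), naalad2 (-2.87 ± 0.54), epdl2 (-2.84 ± 0.47), the amino acid transporter gene slc7a7 (-2.82 ± 0.39), tpte (-2.68 ± 0.34), the haem synthesis gene urod (-2.61 ± 0.28) and the cytochrome P450 gene cyp2k22 (-2.55 ± 0.25) completed the 12 lowest, with adjusted p between 0.00814 and 0.0399.

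**Figure D1:**
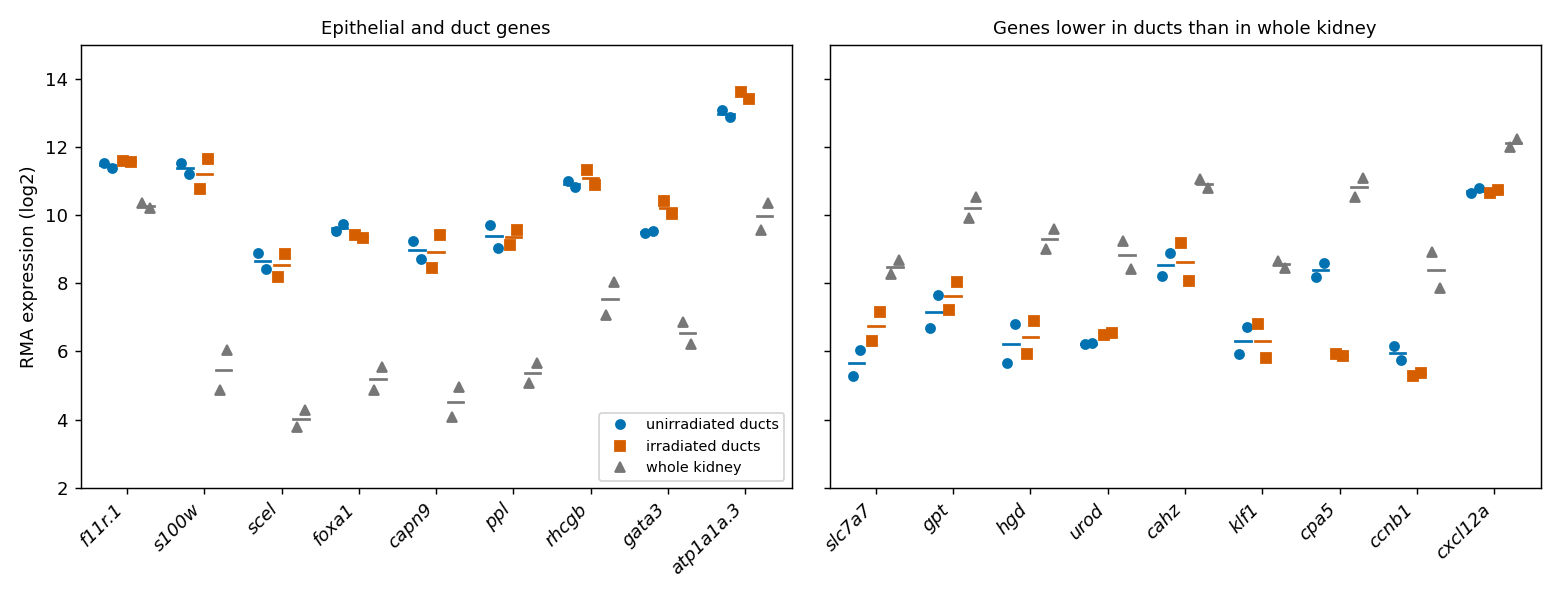
Log2 RMA expression (y axis) of 18 genes (x axis) in unirradiated ducts (circles), irradiated ducts (squares) and whole kidney (triangles), with 1 symbol per array and a bar at each group mean. The duct arrays lie above whole kidney in the left panel and below it in the right panel, as for s100w at 11.38 against 5.46.

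Camera called tight junction and epithelial keratin genes upward in ducts (adjusted p = 1.02e-16), and with an estimated correlation the adjusted p = 0.41. Of 40 measured members, 19 were higher, none was lower and 21 did not pass, and 29 were higher when adjusted over the list alone. Examples were ppl, which encodes periplakin (4.01 ± 0.33), the claudin gene cldne (3.52 ± 0.28) and the keratin gene krt4 (3.32 ± 0.47). Distal tubule and collecting duct markers were higher for 10 of 35 members, and lower for 0 (14 higher and 1 lower when adjusted over the list alone). The ammonia transporter genes rhcgb (3.35 ± 0.35) and rhbg (2.70 ± 0.30), the sodium pump subunit gene atp1a1a.3 (3.01 ± 0.29) and the transcription factor gene gata3 (2.96 ± 0.26) led this list. Proximal tubule markers were lower for 5 of 21 members and higher for 1 (10 and 2 when adjusted over the list alone), with the endocytic adaptor gene dab2 at -2.33 ± 0.48 and the oxidase gene hao1 at -2.27 ± 0.40. The vacuolar proton pump, which acidifies urine and organelles, had 2 of 15 subunit genes lower, atp6v1e1b (-1.21 ± 0.18) and atp6v1h (-0.87 ± 0.17), and 4 lower when adjusted over the list alone. Camera tests with a preset correlation gave adjusted p of 2.87e-06 for distal markers, 0.000912 for proximal markers and 0.0125 for the pump. With an estimated correlation the adjusted p = 0.41 for distal markers and the pump, and the adjusted p = 0.454 for proximal markers.

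Among 28 erythroid genes 9 were lower and 0 higher (15 lower when adjusted over the list alone), including the carbonic anhydrase gene cahz (-2.38 ± 0.42) and the globin regulator klf1 (-2.23 ± 0.40). Of 33 myeloid genes, 5 were lower and 0 higher (13 lower and 1 higher when adjusted over the list alone), with the carboxypeptidase gene cpa5 at -2.43 ± 0.25 and the leukocyte actin-bundling gene lcp1 at -1.34 ± 0.21. Proliferation genes were lower for 18 of 82 members, and for 59 when adjusted over the list alone, with the cyclin gene ccnb1 at -2.43 ± 0.36 and the replicative helicase gene mcm7 at -1.99 ± 0.33. DNA repair genes were lower for 2 of 46, rpa2 (-1.25 ± 0.20) and lig1 (-0.84 ± 0.17), and for 5 when adjusted over the list alone, and the proliferation list also holds both genes. Camera gave adjusted p of 1.8e-07 for erythroid, 0.00371 for myeloid, 1.02e-16 for proliferation and 0.0125 for repair genes. With an estimated correlation the adjusted p = 0.431 for erythroid and proliferation, the adjusted p = 0.423 for myeloid and the adjusted p = 0.588 for repair genes.

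Of 41 members of the haematopoietic niche list, mostly ligands with Notch ligands and the prostaglandin synthesis gene ptgs2a among them, 6 were higher, 1 was lower and 34 did not pass (8 higher and 1 lower when adjusted over the list alone). The growth factor genes pdgfab (2.47 ± 0.21), mdka (2.45 ± 0.36), fgf10a (2.04 ± 0.25) and wnt11 (1.63 ± 0.28) were higher. The single lower member, named here after its values were seen, was the chemokine gene cxcl12a, whose product retains blood stem cells in their niche. It was at 10.72 ± 0.11 in ducts and 12.11 ± 0.16 in whole kidney (-1.39 ± 0.17, adjusted p = 0.0137). Camera called the list upward (adjusted p = 0.00857), and with an estimated correlation the adjusted p = 0.41.

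Immediate early genes were higher for 8 of 37 and lower for 1 (15 and 2 when adjusted over the list alone), with ier2a at 2.43 ± 0.38, junbb at 2.43 ± 0.39 and the phosphatase gene dusp4 at -2.34 ± 0.30. Inflammatory and acute phase genes were higher for 9 of 33 and lower for 3 (14 and 7 when adjusted over the list alone), with the chemokine gene ccl19a.1 at 2.23 ± 0.24 and the protease inhibitor gene timp2b at -2.20 ± 0.31. Interferon and antigen presentation genes had 0 of 22 past the threshold by either adjustment. Oxidative stress genes were lower for 7 of 35 and higher for 1 (14 and 1 when adjusted over the list alone), with the glutathione enzyme genes gstt1a (-1.99 ± 0.27), gclm (-1.79 ± 0.30) and gpx1b (2.48 ± 0.43). Camera called the first 3 lists upward and oxidative stress genes downward, with adjusted p of 2.87e-06, 0.029, 0.000912 and 0.00195 in this order. In the same order, the adjusted p = 0.41, the adjusted p = 0.423, the adjusted p = 0.436 and the adjusted p = 0.431 with an estimated correlation.

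Markers of muscle moved with the ducts as well. Skeletal muscle genes were higher for 7 of 23 members and positive in all 23 (14 higher when adjusted over the list alone), including acta1a (3.07 ± 0.60) and tnnt3b (2.90 ± 0.53). Camera gave an adjusted p of 5.56e-10, and with an estimated correlation the adjusted p = 0.423. For the muscle actin gene actc1b the probe set used read 2.50 ± 0.21, while another of its probe sets was lower in ducts (-1.40, adjusted p = 0.0489). In the list of endothelium and stroma 4 of 20 genes were higher and 3 lower (9 and 4 when adjusted over the list alone), and the smooth muscle genes tagln (3.99 ± 0.64) and acta2 (3.67 ± 0.73) and the matrix gene postnb (3.99 ± 0.79) had the largest values.

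The remaining lists did not pass camera, with adjusted p between 0.0997 and 0.785. Thrombocyte genes had 2 of 6 higher, fn1b (2.79 ± 0.31) and thbs1b (2.45 ± 0.41), both also matrix genes, and 1 lower, nfe2 (-1.57 ± 0.25). Blood stem and progenitor genes had 2 of 19 higher and 2 lower, with gata2a at 1.81 ± 0.32, tal1 at -2.20 ± 0.34 and myb at -1.15 ± 0.24. The p53 targets had 2 of 37 higher and 2 lower, with gadd45bb at 1.65 ± 0.17 and mdm2 at -0.90 ± 0.17. Liver, pancreas and gonad genes had 3 of 39 lower, the largest fall being apoea (-1.47 ± 0.19). Adjusted over the list alone, the higher and lower counts were 2 and 2 for thrombocyte, 2 and 5 for stem and progenitor, 2 and 2 for p53 targets, and 0 and 3 for liver, pancreas and gonad. No member passed among 6 podocyte, 10 interrenal and chromaffin, 37 heat shock, 78 ribosomal protein and 85 oxidative phosphorylation genes by either adjustment, while 10 lymphoid genes had 0 past the threshold and 1 lower when adjusted over the list alone. Median, mean and test differed in sign for thrombocyte genes (median -0.26, mean 0.33, tested upward), for liver, pancreas and gonad (median 0.02, mean -0.23, downward), for p53 targets (median -0.0013, mean 0.09, upward) and for ribosomal proteins (median -0.02, mean -0.03, upward).

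Whole kidney arrays were less alike than duct arrays, with a root mean square SD of 0.465 against 0.246 in unirradiated and 0.250 in irradiated ducts. The count was 0 without unirradiated duct replicate 1 or 2 (2777 and 2536 at an unadjusted limma p under 0.05, against 4163 with all arrays), 422 without either irradiated array or on these 2 groups alone (309 higher, 113 lower), 1757 without kidney replicate 1 and 3373 without kidney replicate 2. Centring on the hybridisation controls, which differed by 1.55 between these groups, moved the median of all probe sets from 0.01 to -1.54 and left 35 higher and 1900 lower, so directions here are relative to the median transcript. The GAPDH 3' minus 5' difference was 1.16 and 2.52 in the unirradiated duct arrays and 0.55 and 0.91 in the kidney arrays. Over 10 alternatives other than the estimated correlation and fry, 8 of the 14 list calls passed in every one, and the calls of proximal tubule, niche, oxidative stress, proton pump, inflammatory and repair genes were lost in 1 or 2.

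The second comparison asked what 25 Gy of irradiation changed in the ducts. The gene of the p53 ubiquitin ligase, mdm2, itself a p53 target, rose from 7.05 ± 0.22 to 9.54 ± 0.03 (SD, n = 2), a 5.60-fold change (log2 fold change 2.48 ± 0.17, adjusted p = 0.0184). Transcripts of 3 leukocyte genes fell with it. The lysozyme gene lyz was 7.86-fold lower (-2.97 ± 0.16, adjusted p = 0.0149), ptprc, which encodes the pan-leukocyte phosphatase CD45, changed by -1.86 ± 0.18 (adjusted p = 0.039), and trac, the constant region of the T cell receptor alpha chain, by -2.69 ± 0.21 (adjusted p = 0.0272). The level of trac in irradiated ducts lay under the array medians, so the size of its fall is uncertain. In all, 12 probe sets rose and 14 fell, each at least 2-fold, and 13 of these 26 had no gene symbol.

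Beside mdm2, the named genes that rose were bmb, a gene of nuclear fusion in early embryos (2.99 ± 0.26), the chemokine family gene cxl34b.11 (2.75 ± 0.23), the interferon-stimulated exonuclease gene isg20 (2.16 ± 0.20), the somatostatin gene sst2 (2.15 ± 0.20) and the ubiquitin ligase gene lnx1 (1.67 ± 0.17), with adjusted p between 0.0276 and 0.0464. The polyamine acetyltransferase gene sat2a.2 fell from 7.63 ± 0.24 to 3.83 ± 0.22 (-3.80 ± 0.23, adjusted p = 0.0149), with whole kidney at 3.86 ± 0.26. These lower levels lie under the array medians, so the size of the fall is uncertain. The gene cpa5 fell as well (-2.50 ± 0.25, adjusted p = 0.0461). The immune checkpoint gene vsir, taken by the rule to fill the falling genes to 6, did not pass (-1.59 ± 0.17, adjusted p = 0.0562). The other 2 probe sets of trac read -0.03 and -0.86 and did not pass either.

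**Figure D2:**
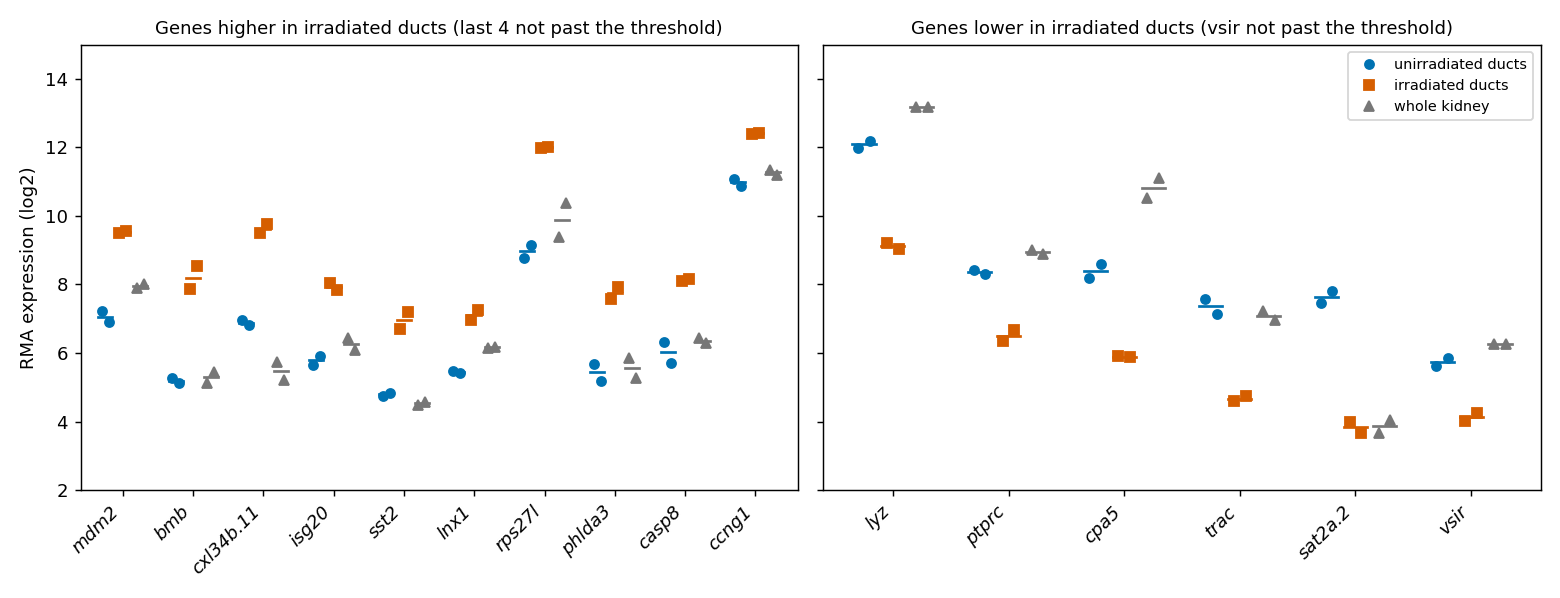
Log2 RMA expression (y axis) of genes (x axis) in unirradiated ducts (circles), irradiated ducts (squares) and whole kidney (triangles), with 1 symbol per array and a bar at each group mean. The irradiated arrays lie above the unirradiated ones on the left, as for mdm2 at 9.54 against 7.05, and below them on the right, as for lyz at 9.12 against 12.10.

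The p53 targets had 1 of 37 past the threshold, and 7 higher and 1 lower when adjusted over the list alone. Among these, and named after their values were seen except ccng1, were the ribosomal protein homologue gene rps27l (3.04 ± 0.34, adjusted p = 0.0606), phlda3 (2.32 ± 0.29, adjusted p = 0.0806), the caspase gene casp8 (2.11 ± 0.23, adjusted p = 0.06) and the cyclin gene ccng1 (1.43 ± 0.16, adjusted p = 0.0606). Camera called the list upward (adjusted p = 0.00261), and with an estimated correlation the adjusted p = 0.6.

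Interferon and antigen presentation genes had 1 of 22 past the threshold, isg20, and 3 higher when adjusted over the list alone. Inflammatory and acute phase genes had 0 of 33, and 7 higher and 1 lower when adjusted over the list alone. Among those was irg1l, an itaconate synthesis gene named after its values were seen (3.07 ± 0.33, adjusted p = 0.0543). Both lists were called upward by camera, with adjusted p of 0.00105 (0.0834 without irradiated replicate 2) and 0.00261. Their adjusted p = 0.6 and adjusted p = 0.465 with an estimated correlation.

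Myeloid genes had 3 of 33 lower, lyz, cpa5 and ptprc, and 10 lower and 1 higher when adjusted over the list alone. The higher one was the myeloperoxidase gene mpx (1.47 ± 0.40, adjusted p = 0.246), named after its values were seen. Lymphoid genes had 1 of 10 lower, trac, and 2 when adjusted over the list alone. Erythroid genes had 0 of 28 past the threshold and 1 lower when adjusted over the list alone. That gene was the globin gene hbba2 (-1.96 ± 0.28, adjusted p = 0.103), while the globin gene hbaa1 read 0.24 ± 0.23 (adjusted p = 0.669). Camera gave adjusted p of 5.65e-06 for myeloid, 0.00176 for lymphoid and 0.77 for erythroid genes. For both leukocyte lists the adjusted p = 0.465 with an estimated correlation, which was -0.0819 for lymphoid and 0.0628 for myeloid genes. Fry gave an adjusted p of 0.00959 for lymphoid and 0.0905 for myeloid genes.

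Proliferation genes were called downward by camera although no member passed. Their median was -0.53 and 76 of 82 were below 0, with hmgb2b at -0.65 ± 0.21 (adjusted p = 0.291) and pcna at 0.08 ± 0.37 (adjusted p = 0.938). The camera adjusted p was 1.8e-09, and with an estimated correlation the adjusted p = 0.606. Skeletal muscle genes were below 0 in all 23 members, with 0 past the threshold, 1 lower when adjusted over the list alone and ckmb at -1.42 ± 0.75 (adjusted p = 0.447). Of these members 22 were higher in unirradiated replicate 2 than in replicate 1, with a median difference of 1.06. The size of the fall thus depends on that replicate. Camera gave an adjusted p of 5.65e-06 (0.0517 without unirradiated replicate 2), and with an estimated correlation the adjusted p = 0.6.

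Camera also called interrenal and chromaffin genes (0 of 10, adjusted p = 0.0255), DNA repair genes (0 of 46, adjusted p = 0.0399) and ribosomal proteins (0 of 78, adjusted p = 0.0496) downward. It called apical junction genes (0 of 40, adjusted p = 0.0107), oxidative phosphorylation genes (0 of 85, adjusted p = 0.00817) and heat shock genes (0 of 37, adjusted p = 0.0496) upward. With an estimated correlation the adjusted p = 0.6 for interrenal and heat shock, the adjusted p = 0.772 for repair, the adjusted p = 0.796 for ribosomal, the adjusted p = 0.606 for junction and the adjusted p = 0.768 for oxidative phosphorylation genes. The keratin gene krt8 read 0.52 ± 0.17 (adjusted p = 0.295). Adjusted over the list alone, 1 ribosomal protein list member was higher, rps27l, which the p53 list also holds, and no member of the other 5 lists passed. Over up to 10 alternatives, with arrays left out among them, the call was kept in 8 for junctions, 6 for interrenal, 6 for repair, 6 for oxidative phosphorylation, 5 for heat shock and 2 for ribosomal genes.

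Niche factors had 0 of 41 past the threshold after irradiation, and 1 higher when adjusted over the list alone (camera adjusted p = 0.82). Here cxcl12a was at 10.69 ± 0.08 in irradiated ducts (-0.03 ± 0.17, adjusted p = 0.958), pdgfab read -0.47 ± 0.21 (adjusted p = 0.38) and igf2b 0.73 ± 0.19 (adjusted p = 0.239). No member passed either among 35 distal tubule, 21 proximal tubule, 6 podocyte, 6 thrombocyte, 19 stem and progenitor, 20 endothelium and stroma, 39 liver, pancreas and gonad, 37 immediate early, 35 oxidative stress and 15 proton pump genes, with camera adjusted p between 0.113 and 0.957. Adjusted over the list alone, 1 podocyte gene was higher, and 1 thrombocyte, 1 stem and progenitor and 1 endothelium and stroma gene were lower. Median, mean and test differed in sign for erythroid genes (median 0.06, mean -0.06, tested downward), endothelium and stroma (median -0.02, mean 0.07, upward) and niche factors (median -0.03, mean 0.08, upward).

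**Figure D3:**
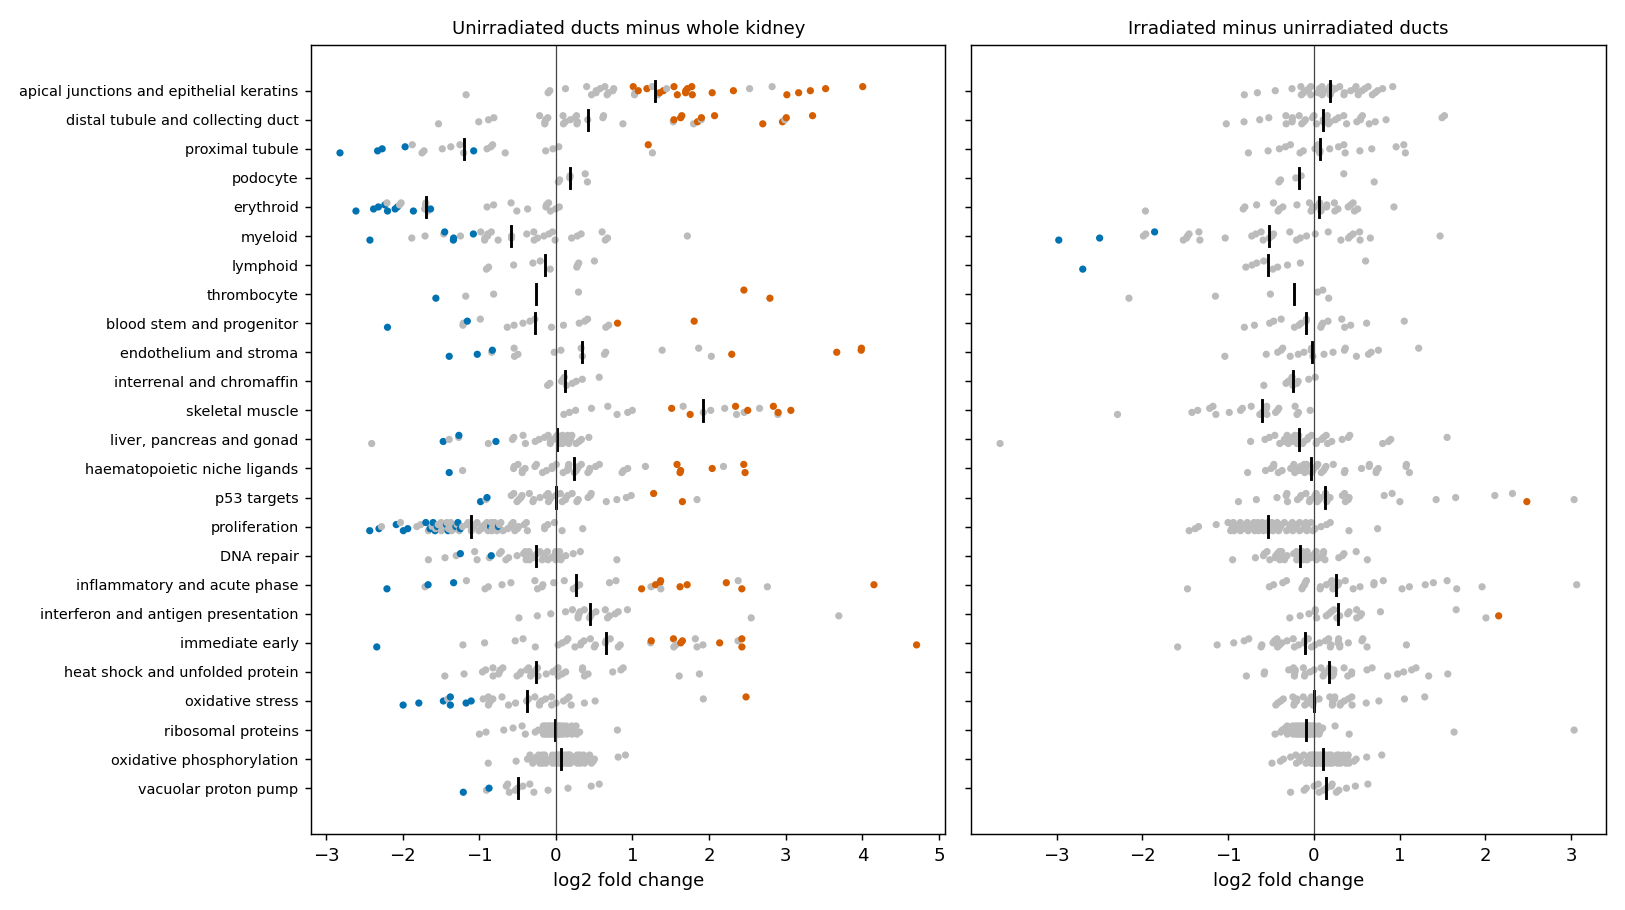
Log2 fold change (x axis) of each measured member of 25 gene lists (y axis) for unirradiated ducts minus whole kidney (left) and irradiated minus unirradiated ducts (right). Orange points are higher and blue points lower at an adjusted p under 0.05, grey points did not pass, vertical bars are list medians and the vertical offset within a list only separates points. Of the proliferation genes, 18 pass on the left and 0 on the right.

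Some array controls separated the duct groups as well. The hybridisation controls averaged 10.90 ± 0.34 in unirradiated and 9.51 ± 0.17 in irradiated ducts, and the 5' probe set of the dap poly-A control 5.35 ± 0.32 and 7.62 ± 0.16. The dap 3' probe set overlapped, at 7.41 and 9.01 in unirradiated and 8.81 and 9.04 in irradiated ducts. The GAPDH 3' minus 5' difference was 1.16 and 2.52 in the unirradiated and 1.13 and 0.97 in the irradiated duct arrays. The count of 26 became 0 without unirradiated replicate 1 or 2 or irradiated replicate 1 or 2 (1658, 923, 1186 and 1058 at an unadjusted limma p under 0.05, against 2212 with all arrays), and 217 on the duct arrays alone or without either kidney array (88 higher, 129 lower). Centred on the hybridisation controls, 147 were higher and 0 lower, and the median of all probe sets moved from -0.05 to 1.34, so directions here too are relative to the median transcript.

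**Figure D4:**
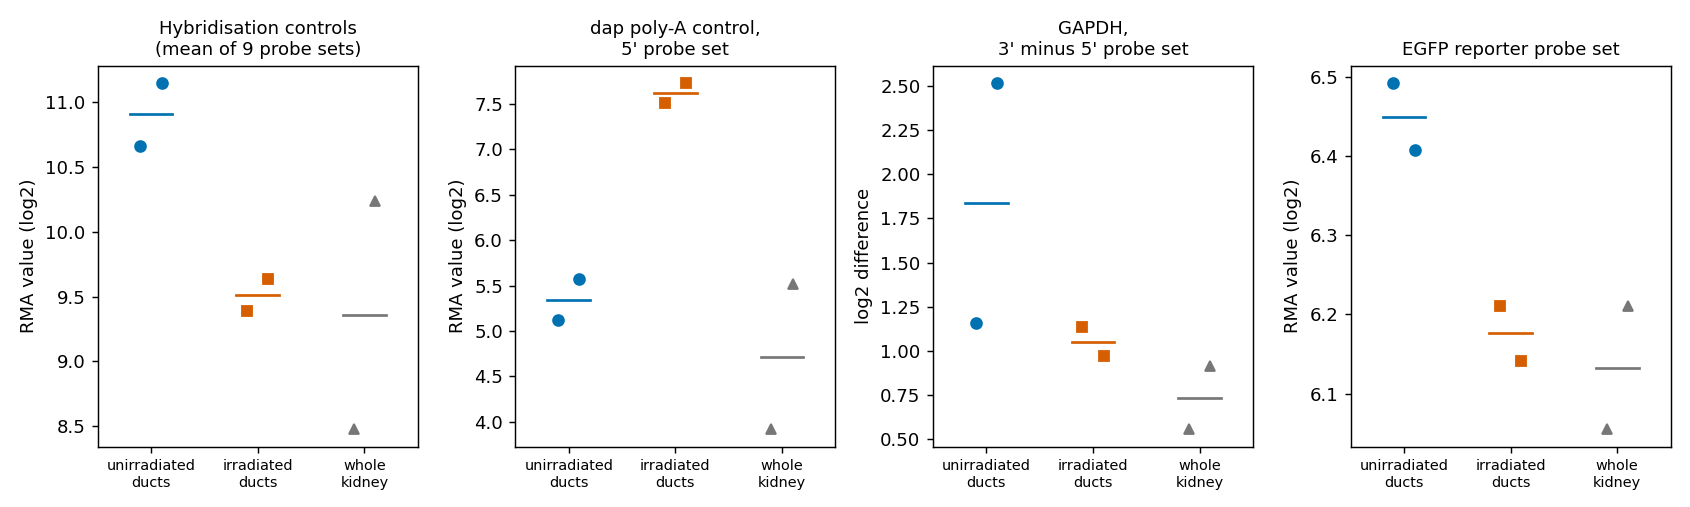
Log2 RMA value, or log2 difference for GAPDH 3' minus 5' (y axes), of array controls and of the EGFP probe set in unirradiated ducts, irradiated ducts and whole kidney (x axis), with 1 symbol per array and a bar at each group mean. The hybridisation controls average 10.90 in unirradiated ducts and 9.51 in irradiated ducts.

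Irradiated ducts were also set against whole kidney. Here 963 probe sets were higher and 657 lower, 831 and 543 of them at least 2-fold. Among the genes named above, s100w was at 11.20 ± 0.64 and foxa1 at 9.36 ± 0.06 in irradiated ducts, against 5.46 ± 0.83 and 5.20 ± 0.47 in whole kidney. On these 2 groups alone or without either unirradiated duct array 511 were higher and 272 lower. The total was 337 and 308 without irradiated duct replicates 1 and 2, 3183 without kidney replicate 2, and 202 (120 higher, 82 lower) when centred on the hybridisation controls, which moved the median of all probe sets from -0.05 to -0.21.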

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

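The tests on blood-forming tissue and on skeletal muscle carried along were chosen only after the results they measure were seen, while those with the GAPDH covariate were set out before. By the bounds set out before, both covariate tests counted against uneven RNA quality or labelling. They were left open for a reason added after their output, that the covariate measures 3' bias while controls of labelling and hybridisation split the duct groups.

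The first pattern was the lower level of myeloid and lymphoid transcripts in irradiated ducts, with a median log2 fold change of -0.58 (quartiles -1.47 and 0.17) over 33 genes whose kidney mean was at least 7. Against less blood-forming tissue carried along as the whole cause, the 22 erythroid genes at the same minimum had a median of 0.0858 (quartiles -0.16 and 0.27), though the globin gene hbba2 read -1.96 without passing the threshold. Proliferation genes went the other way. In ducts against whole kidney 80 of 82 were below 0, and after irradiation 76 of 82 were, with a median of -0.53. Less blood-forming tissue is therefore not excluded. A loss of leukocytes after irradiation and uneven carry-over of leukocyte-rich material may both account for the pattern and stay open, and mpx read higher, at 1.47. With the GAPDH 3' minus 5' difference of each array as a covariate the median was -0.66 (quartiles -1.56 and 0.03). The median thus did not shrink, but uneven labelling cannot be told apart from irradiation here, since the hybridisation controls and the dap 5' probe set split the duct groups, though dap 3' does not.

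The second pattern was the set of 26 probe sets that differed between the duct groups. With the same covariate their median absolute log2 fold change was 2.53 (quartiles 2.01 and 2.91) against 2.55 without it, and 0 changed sign. The calls ended, with 0 of 26 past the threshold and all 26 at an unadjusted limma p under 0.05, as the residual degrees of freedom dropped to 2 and the median SE went from 0.189 to 0.246. Uneven labelling cannot be told apart from irradiation for these probe sets, for the reason given above. The slope of the covariate rests mostly on the difference between the 2 unirradiated pools. The 26 were also called partly for a small spread within groups, and only that spread sets the slope. Their fold changes could thus hardly shrink, so the covariate fit cannot decide the question. An effect of irradiation stays open beside it.

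The third pattern was the higher level of skeletal muscle transcripts in ducts. Of 23 members, 22 were higher in unirradiated pool 2 than in pool 1, with a median difference of 1.06 (quartiles 0.39 and 1.82), while random lists of like level held a central 95 percent from -0.13 to 0.14. Such lists hold unrelated genes, whereas the muscle genes had an estimated correlation of 0.53, so the range is no fair reference. That correlation was estimated from the residuals of the same arrays, which include this pool difference, so it is no independent evidence. Other lists differed between these pools as well, with medians of 0.78 for proximal tubule and 0.41 for erythroid genes. So did the GAPDH 3' minus 5' difference, at 1.16 in pool 1 and 2.52 in pool 2. In irradiated against unirradiated ducts all 23 members were below 0, with a median of -0.60. Muscle carried along in the dissection may account for the pattern but cannot be told apart from other differences between the pools, and no biological explanation was tested.

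Some signals outside the main measurement are given here. The EGFP probe set averaged 6.45 ± 0.06 (SD, n = 2) in unirradiated ducts, above 6.13 ± 0.11 in whole kidney, and 6.18 ± 0.05 in irradiated ducts. The irradiated arrays, at 6.21 and 6.14, overlapped the kidney arrays, at 6.05 and 6.21, so the probe set did not mark both duct groups. The DsRed probe set read 5.26 and 5.60 in unirradiated ducts, 6.50 and 5.98 in irradiated ducts, and 5.03 and 5.31 in whole kidney. AsRed read 5.73 and 5.69, 5.52 and 5.32, and 5.18 and 5.84 in this order. The hybridisation controls averaged 10.90 ± 0.34 in unirradiated ducts, above 9.36 ± 1.24 in whole kidney. The 5' probe set of the dap poly-A control averaged 7.62 ± 0.16 in irradiated ducts, above 5.35 ± 0.32 in unirradiated ducts.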

How the results depend on the processing

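All alternatives here were set out before the data were examined. For unirradiated ducts against whole kidney the 1126 probe sets became 812 with the replicate block, 1048 with trend and robust, 1109 with the filter, 422 on the 2 groups alone, 615 with array weights, 1935 with spike-in centring (35 higher, 1900 lower), 2330 at an adjusted p under 0.1, 235 against a fold of 1.5, 697 at gene level and 0 to 3373 when 1 array was left out. For irradiated against unirradiated ducts the 26 became 0 with the replicate block (1906 at an unadjusted limma p under 0.05), 30 with trend and robust, 20 with the filter, 217 on the 2 groups alone, 243 with array weights, 147 with spike-in centring (147 higher, 0 lower), 65 at an adjusted p under 0.1, 9 against a fold of 1.5, 9 at gene level and 0 to 217 when 1 array was left out. For irradiated ducts against whole kidney the 1620 became 1393 with the replicate block, 1658 with trend and robust, 1261 with array weights, 1554 with the filter, 783 on the 2 groups alone, 202 with spike-in centring, 2604 at an adjusted p under 0.1, 466 against a fold of 1.5, 1098 at gene level and 308 to 3183 when 1 array was left out. The replicate numbers are shared between groups only as numbers, and deviations from group means correlated across probe sets at -0.0976, 0.0633 and -0.0972. Leaving out an array of the group not compared equals the fit on 2 groups by construction, and a wider threshold, a minimum fold and fewer features change a count by construction. Spike-in centring moves all log2 fold changes of a comparison by the same amount, so its shift of directions follows by construction. The replicate block leaves fewer residual degrees of freedom. The fit on the duct arrays alone leaves out the kidney arrays, whose spread was larger (0.465 against 0.246 and 0.250). Beyond this, the cause of the other shifts was not tested.

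The 14 lists of the first comparison became 0 with an estimated correlation, 3 with fry, 14 with the replicate block, 14 with medians of probe sets, 15 with the filter, 14 with spike-in centring and 11 to 14 when 1 array was left out. The 13 lists of the second became 0, 1, 11, 13, 10, 10 and 8 to 12 in this order. The lists past fry in the first comparison were apical junctions (adjusted p = 0.0199), niche factors (0.0144) and the proton pump (0.0144). In the second it was the lymphoid list (0.00959). Apart from the estimated correlation and fry, 8 of the 14 and 5 of the 13 passed in every alternative, and none of the called lists turned direction. The 5 were myeloid, lymphoid, p53 targets, proliferation, and inflammatory and acute phase. These alternatives all kept the preset correlation, so they do not test it. The proliferation list had an estimated correlation of 0.572, and fry gave it an adjusted p of 0.429.

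Of 75 genes with a value in the first comparison, all 75 were no longer past the threshold without either unirradiated duct array and 29 on the 2 groups alone. Of 29 in the second, the 11 past the threshold were lost with the replicate block and without any duct array. With spike-in centring 22 of the 75 and 5 of the 29 were no longer past the threshold without a change of sign, and the sign turned for f11r.1 in the first comparison (-0.36) and, in the second, for hmgb2b (0.75), actc1b (0.84), pdgfab (0.92) and cxcl12a (1.36), none of them past the threshold there. This centring lowers every log2 fold change of the first comparison by 1.55 and raises every one of the second by 1.39. The turned signs therefore follow by construction. Of the 29 genes in the second comparison, 5 came past the threshold with this centring. With array weights 7 did, and on the 2 groups alone 7, with 0 lost in either. When 1 array was left out, cxcl12a ranged from -0.11 to 0.053, including 0.03 without irradiated replicate 1, and pcna from -0.14 to 0.31. Leaving out a duct array leaves fewer residual degrees of freedom and 1 array in its group. It also gives the kidney pair, whose spread was larger, more weight in the shared spread. Beyond this, the cause of the lost calls and of these ranges was not tested. Levels near the lower end of the scale carry little signal over background. The filter acts on the mean over all arrays, so it leaves in genes that are low in 1 group alone.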

Other observations

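Every observation in this part was chosen after the values were seen, and no test was added. The smooth muscle gene tagln was at 11.80 ± 0.13 (SD, n = 2) in unirradiated and 11.38 ± 0.51 in irradiated ducts, and acta2, which encodes smooth muscle actin, at 12.19 ± 0.08 and 12.08 ± 0.44. In whole kidney they were at 7.82 ± 1.41 and 8.53 ± 1.66.

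The whole kidney pools differed from each other in several transcripts. The keratin gene krt5 was at 5.64 in replicate 1 and 10.67 in replicate 2, the histocompatibility gene mhc1ufa at 10.12 and 4.19, and the apolipoprotein gene apoa2 at 8.61 and 12.92. In ducts, apoa2 was at 9.90 and 10.51 without irradiation and at 7.45 and 5.64 with it.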
